A study of Mus musculus with 30 samples.

How the data were processed

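Libraries were made with the NEXTflex small RNA kit from RNA that had been extracted from pulverised organs with a phenol-based reagent, per the labels' protocols. Reads were counted with featureCounts (Subread 2.0.3) on the GRCm39 mouse genome and compared with DESeq2, per the submitters' processing notes. The aligner, the annotation, the treatment of reads that match several genes and the DESeq2 model are not given in the sources used here. Reads of near-identical precursors, such as the copies of a let-7 gene, may therefore be split or shared in ways that could not be checked.

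The authors deposited 1 table per organ with 2195 rows and no values per sample. The deposited mean is a signal, the mean over an organ's libraries of counts divided by size factors, per the file headers and the submitters' processing notes. The deposited fold change and its standard error are on the log2 scale, per the file headers. The deposited Wald statistic is a score, which equals the fold change over its standard error. The deposited p-value and adjusted p-value belong to that statistic, per the file headers. The authors' tables do not say which genotype is the numerator. Of the 2195 rows, 1 has no name and was left out, and it held at most 1.82e-05% of an organ's total. The number of unused columns with values per sample was 0.

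The design fixed before the data were examined assumed counts per library. The tables hold the authors' comparison only, so the fallback fixed with it was used: the authors' adjusted p at a threshold of 0.05. A feature was called where the deposited adjusted p was below 0.05. Some features have a statistic and no p-value, 3 in kidney and 5 in liver, and they were kept out of the calls. DESeq2 withholds a p-value where the count of a library is an outlier by Cook's distance, but the tables do not state the reason. In heart 355 of 1107 p-values carry an adjusted p, and in the other organs all do.

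Named features followed a rule fixed in advance. Per organ it took up to 12 features of each sign past the threshold, the 5 with the smallest p where fewer than 5 passed, up to 4 members of each list past the threshold or else the 2 most abundant, any feature past the threshold in 2 organs, and the 3 with the highest mean. Features outside the rule were chosen after their values were seen. These are Mir125a, Mir125b-1, Mir802, Mir6236, Mir6969, Mir216a, Mir216b, Mir7b, Mir8120, Mir466n, Gm54588, Gm54610, and members of the let-7 family beyond the most abundant, as well as Mir128-2 and Mir338 in brain and Mir204 and Mir10b in kidney. Members are named as precursors, since the tables do not separate the arms of a hairpin.

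There were 24 fixed microRNA lists with 251 precursors. Some planned members were matched to no feature by symbol and are not analysed here: miR-124 (neuron), miR-122b (hepatocyte), miR-142a and miR-146a (leukocyte, the latter also inflammation-induced), miR-486a and miR-486b (red cell), let-7k, and miR-18a and miR-92a (miR-17/92). The shares and counts of these lists cover the matched members alone. A list was tested where at least 3 members had a statistic. Its mean deposited statistic was set against 100000 random lists matched on mean level in 10 bins, two-sided, with Benjamini-Hochberg adjustment over the lists of an organ. Each list's members were also adjusted over the list alone. Differences between organs were z-scores of 2 deposited fold changes over their combined standard errors, which treats the organs as independent. The let-7 list was tested between organs in the same way as the lists, a test chosen after its values were seen. Features named Gm were tested as a class with 20000 draws.

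Means under 1 were used to find 6 size factors per organ, since each such mean is a sum of whole reads divided by those factors. The factors explained 228 to 355 low means per organ at a tolerance of 1e-11. Low features were then split into whole reads per library at a relative tolerance of 3e-14, which gave 1 solution for each feature printed. A fold against a side with 0 reads used a floor of 3 reads over the group and covers counting error only. It is a lower bound with respect to the side with 0 reads alone, since the reads of the other side are taken as counted. Folds without the library of the highest normalized count were added after seeing the data. Precision is limited by 3 libraries per genotype and organ and by the read count of low features.

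Steps were tested on simulated data. For the list test on 1107 heart features, 7 of 100 unshifted lists of 10 passed p 0.05, and 100 of 100 passed with the statistic shifted by 1.5. The simulated statistics were independent draws and the lists random, so correlation between members of a family was not covered. For the heart and spleen difference on 959 features, 58 of 200 changed features were recovered at a log2 difference of 1 with 1 false call, and 181 at a log2 difference of 3 with 8 false calls. All 40 simulated means were split into their exact reads. These means lay under 40 and the side of each library was known. Mir34b in heart and Mir6969 in liver had higher means, which the simulation did not cover.

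Names were matched to a RefSeq table of assembly GRCm38.p6, a different build, used only for names and host genes. It matched 1174 of 1189 microRNA symbols and 2 of 1004 Gm symbols, and no coordinates were taken from it. Alternatives covered the adjustment without a filter, a mean of at least 10, other thresholds, a minimum size of the change, unmatched draws, 1 precursor per mature sequence, a sign test, read only for lists whose most extreme outcome could pass after adjustment, and features without a p-value taken in. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.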

Results

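Small RNA was sequenced from brain, heart, kidney, liver and spleen of 6 male mice aged 4 months, 3 deficient in Ftsj1 and 3 wild type. Each organ gave 6 libraries, 30 in all. Ftsj1 encodes a methyltransferase that places 2'-O-methyl groups on tRNA, and the question was how its loss alters microRNA levels in each organ. Ftsj1 is read as an mRNA, which these small RNA tables do not count, so the genotype labels could not be checked from these values. The authors' deposited table for each organ holds 2194 named features, of which 1189 carry microRNA symbols (Mir or Mirlet), 1004 carry provisional Gm symbols and 1, Snord43, is a small nucleolar RNA. Mean normalized counts summed to 16119031 in brain, 8511372 in heart, 21787131 in kidney, 18941389 in liver and 10737328 in spleen. Each table gives a fold change between the genotypes without naming the genotype in the numerator. Values are therefore given with their sign only, and comparisons of sign between organs assume the same numerator in all 5 tables. Heart, kidney and liver each include 1 wild-type library of a second sequencing batch, and no within-batch value could be had because the libraries of that batch could not be identified in the tables. For low features, whole read counts of the 6 libraries were recovered from the deposited means, and the 3 libraries that raise a fold change are called the positive side and the other 3 the negative side. These libraries could not be assigned to single mice.

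The organs differed in their abundant microRNAs in the way their labels name. Neuron-enriched microRNAs, a list that includes the Mir9 and Mir128 precursors, made up 21.6% of the brain total, with miR-124 not matched, in the authors' deposited table, 61.2 times the next organ. Oligodendrocyte microRNAs of the Mir219 and Mir338 precursors made up 0.382% in brain, of which Mir219a-2 alone gave 0.381%. Mir338 stood at 4.68e-05% in brain, and Mir219a-1 was highest in spleen, in the authors' deposited tables. The Mir338 mean was under 10 normalized counts. Whether it reflects the level in the tissue or the way reads were counted could not be checked. Striated muscle microRNAs, among them Mir1a-1 and Mir133a-1, made up 11.6% in heart, and 8 of the 9 members with counts were highest there. Mir122, the abundant microRNA of hepatocytes, made up 26.2% in liver. Kidney-enriched microRNAs, mostly Mir10a, Mir10b and Mir30a, made up 22.1% in kidney, 2.97 times the next organ. Of the 9 members of that list 6 were highest in kidney, and Mir204, at 0.0124% in kidney and 0.397% in brain in the authors' deposited tables, was not. Leukocyte microRNAs, including Mir150, Mir155 and Mir223 and with miR-142a and miR-146a not matched, made up 1.62% in spleen, 7.89 times the next organ. All 6 lists were highest in the organ fixed for them before the data were examined, by share of the total and by mean rank. The tables were normalized separately, so these levels describe each organ and were not tested.

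**Figure D1:**
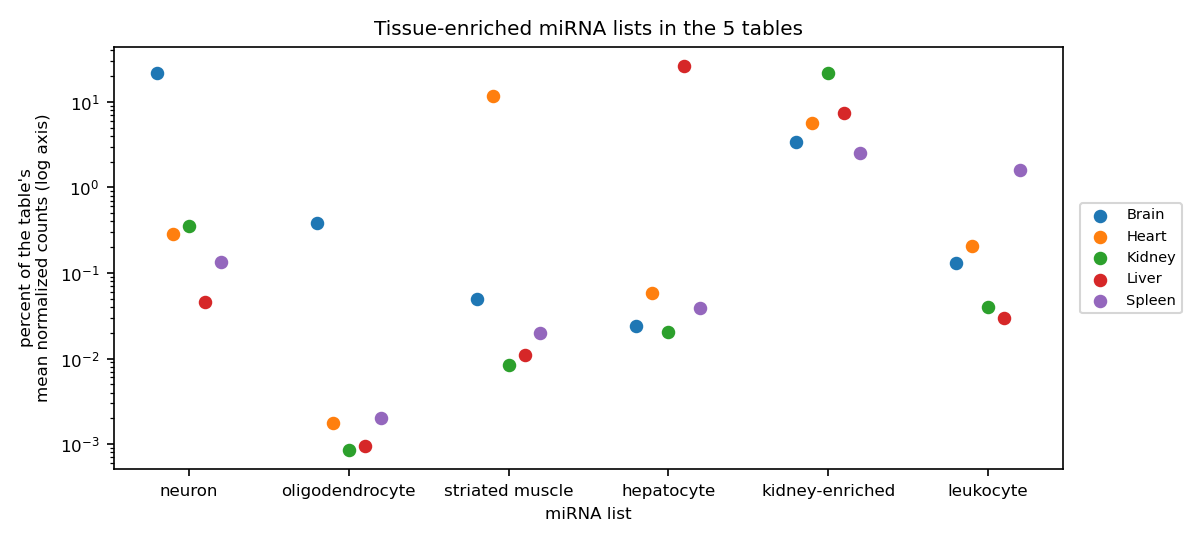
Level of 6 tissue-enriched microRNA lists in each organ, in percent of the organ's total mean normalized count, on a log axis. Each list is highest in the organ it was fixed for, from 0.382% for the oligodendrocyte list in brain to 26.2% for Mir122 in liver.

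In heart, 4 features passed an adjusted p of 0.05 in the authors' deposited table, 3 with a positive and 1 with a negative log2 fold change. Gm56194, a provisional gene with a mean of 9362 normalized counts, changed by log2 1.18 (standard error 0.26), or 2.26-fold, with a DESeq2 adjusted p of 0.00219 in the authors' deposited table. Gm54453 changed by log2 1.15 (standard error 0.31) and Mir6239 by log2 1.09 (standard error 0.29), with adjusted p of 0.0243 and 0.0226 in the authors' deposited table. Mir34b, a member of the miR-34 family that p53 induces, changed by log2 -2.23 (standard error 0.60; adjusted p 0.0226) in the authors' deposited table. Its 441 recovered reads gave 198, 48.9 and 81.0 normalized counts in the libraries of the negative side and 9.92, 30.3 and 27.9 in those of the positive side. The means of the sides differed 4.81-fold, and 2.86-fold without the library at 198. Mir34c, which shares a primary transcript with Mir34b, had a log2 fold change of -1.26 (standard error 0.45) and an adjusted p of 0.131 in the authors' deposited table. Mir34a, encoded at another locus, had a log2 fold change of -0.01 (standard error 0.26) in the authors' deposited table. Mir6538 came next by p, at log2 0.79 and an adjusted p of 0.0553 in the authors' deposited table. The most abundant features, Mir143, Mir1a-1 and Mir30d, had log2 fold changes of 0.07, -0.05 and 0.08 in the authors' deposited table. Of 1107 features with a p-value, 355 also carried an adjusted p. When the adjustment ran over all 1107, Gm56194 stayed past 0.05, while Mir6239 and Mir34b moved to 0.0705 and Gm54453 to 0.0756.

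Among the fixed microRNA lists in heart, 3 of 18 tested passed. The let-7 family, which restrains growth and is abundant in differentiated tissue, had a negative log2 fold change in 10 of 10 measured members, with a median of -0.65 (permutation p = 7e-05, adjusted p = 0.00126). The combined miR-34 and miR-449 list had a negative sign in 4 of 5 members (adjusted p = 0.0188), and 2 of them passed when adjusted over the list alone against 1 over all features. Those members are Mir34b and Mir34c. The miR-17/92 clusters, whose members promote proliferation, had a positive sign in 11 of 12 matched members, which leave out miR-18a and miR-92a, with a median of 0.41 over the 9 with a mean of at least 10 (adjusted p = 0.0192). With 1 precursor per mature sequence the miR-17/92 adjusted p was 0.0677, and with an exact sign test it was 0.082. No member of the let-7 or miR-17/92 lists passed when adjusted over the list alone. Of 12 let-7 precursors in each organ, 10 had a statistic, and the others were not measured. The list tests permute features, so their p does not measure variation between mice. The imprinted Dlk1-Dio3 cluster had a negative sign in 25 of 36 members, with an adjusted p of 0.0736. This was 0.00108 with draws not matched on level, 0.0113 over features with a mean of at least 10 and 0.0101 in an exact sign test. The neuron list had a negative sign in 12 of 15 members in heart, with an adjusted p of 0.429 by permutation and 0.0211 in an exact sign test. The other lists tested in heart had adjusted p up to 0.958.

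In liver, 2 low features passed, 1 of each sign. Mir294, a member of the miR-290 cluster of embryonic stem cells, had 33, 69 and 62 reads in the libraries of the negative side and 0 in those of the positive side. With a floor of 3 reads over the group, this is a difference of at least 19.5-fold, or 16.1-fold without the highest library, and the authors' deposited table gives an adjusted p of 0.0418. At the rate of the negative side, 58.4 reads would have been read on the positive side. Mir1958 had 26, 6 and 6 reads on the positive side and 0 on the negative side, at least 35.6-fold, or 15.5-fold without the highest library, with an adjusted p of 0.0418 in the authors' deposited table. Of its 38 reads, 26 came from 1 library. With the features that lack a p-value taken in, 3 features passed, the third being Mir6969 at an adjusted p of 0.028. Of its 154 reads, 150 came from 1 library, and DESeq2 withholds a p-value where the count of a library is an outlier, though the tables do not state the reason. The next by p, Mir3474, Mir7083 and Mir7226, had adjusted p of 0.204, 0.274 and 0.366 in the authors' deposited table, with 44, 118 and 103 recovered reads. Mir122, Mir21a and Mir30a, the most abundant, had log2 fold changes of -0.65 (standard error 0.51), 0.09 (standard error 0.34) and 0.12 (standard error 0.40) in the authors' deposited table. Relative depth separated the sides in liver, with size factors of at most 0.729 on the positive side and 1.45 to 2.15 on the negative side.

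Of 17 lists tested in liver, 2 passed. Pancreas microRNAs (Mir216a, Mir216b, Mir217 and Mir375) had a positive sign in 4 of 4 measured members, with a median log2 fold change of 6.52 over the 3 with a mean of at least 10 (permutation p = 1e-05, the smallest the draws can give; adjusted p = 0.00017). Mir216a, Mir217 and Mir375 have a statistic and no p-value in the authors' deposited table, so the list could not be tested without them, nor these members adjusted over the list alone. All 9 recovered reads of Mir216b came from 1 library, the one with the lowest size factor, which also held most of the Mir1958 reads. The miR-200 family, expressed in epithelia, had a positive sign in 5 of 5 members with a median of 0.46 (adjusted p = 0.0234), and 0 of them passed when adjusted over the list alone. That call was lost with permutation draws not matched on level (adjusted p = 0.0794) and over features with a mean of at least 10 (adjusted p = 0.0541). The let-7 family had a negative sign in 9 of 10 members of the liver list, with a median of -0.22 and an adjusted p of 0.552. The 15 lists that did not pass in liver had adjusted p from 0.169 to 0.928.

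In kidney, the let-7 family had a negative log2 fold change in 10 of 10 measured members, with a median of -1.31 (permutation p = 1e-05, adjusted p = 0.00017). They include Mirlet7b, the lowest at log2 -2.62 (standard error 1.16), which has no p-value in the authors' deposited table. Without Mirlet7b the median of the other 9 was -1.28, with a permutation p of 1e-05. Mirlet7c-2, at log2 -1.63 (standard error 0.57), was among the 5 features with the smallest p, and Mirlet7c-1 stood at -1.62 (standard error 0.57) in the authors' deposited table. When adjusted over the list alone, 5 let-7 members passed, against 0 over all features. They are Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7d. Copies of let-7a and of let-7c are among them, so they are not 5 separate microRNAs. Mirlet7g and Mirlet7i, the former the most abundant member, had log2 fold changes of -0.41 (standard error 0.34) and -0.13 (standard error 0.30) in the authors' deposited table. The miR-181 family, known for roles in lymphocytes, had a positive sign in 6 of 6 members with a median of 0.41 (adjusted p = 0.0195), and 0 passed when adjusted over the list alone. The other 15 lists tested in kidney had adjusted p from 0.467 to 0.834. Among them the liver and gut list (adjusted p = 0.577), whose members ran from log2 -1.88 to 0.92, had 2 members past 0.05 when adjusted over the list alone, the smallest at 0.0459. No single feature passed among 1022 tested with DESeq2 in the authors' deposited table, where the smallest adjusted p was 0.331 and 46 features had an unadjusted p under 0.05, 12 positive and 34 negative. The 46 are below a share of 0.05, the share to be had where no feature differs. The smallest p belonged to Mir6940, with 12, 39 and 8 reads on the negative side and 0 on the positive side, at least 22.2-fold, or 11.5-fold without the library that held 39. Mir6953 had 54 and 12 reads in 2 libraries of the negative side, and Mir7236 had 10, 21 and 15 reads on the positive side alone. Mir496a had 59 reads on the negative and 2 on the positive side. Mir143, Mir30a and Mir21a, the most abundant, had log2 fold changes of 0.63 (standard error 0.45), 0.50 (standard error 0.44) and 0.31 (standard error 0.43) in the authors' deposited table.

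In brain, from the same 6 mice, the let-7 family also had a negative sign in 10 of 10 measured members. The median log2 fold change was -0.59 (permutation p = 1e-05, adjusted p = 0.00018). This p comes from permuted features and does not measure variation between mice. The family made up 19.3% of the brain total. No member passed when adjusted over the list alone, where the smallest adjusted p was 0.134. Mirlet7g, the most abundant member, had a log2 fold change of -0.42 (standard error 0.27) in the authors' deposited table. Among 1030 features tested with DESeq2 in the authors' deposited table, 0 passed, with a smallest adjusted p of 0.989, and 23 had an unadjusted p under 0.05, 12 positive and 11 negative. The 23 are below a share of 0.05, the share to be had where no feature differs. Mir3547 (log2 1.62, standard error 0.54), Snord43 (log2 0.80, standard error 0.30) and Mir326 (log2 0.89, standard error 0.34) had the smallest p in the authors' deposited table. Mir6986 had 43 recovered reads on the negative and 9 on the positive side, and Mir7654 had 24 and 6 reads in 2 libraries of the positive side and 0 elsewhere. The neuron list did not pass in brain (adjusted p = 0.904), with 7 positive and 8 negative members that ran from log2 -0.70 to 0.61. The most abundant of them, Mir9-2 and Mir128-1, had log2 fold changes of -0.35 (standard error 0.26) and 0.04 (standard error 0.25) in the authors' deposited table. Mir128-2, named in brain after its values were seen, had the lowest, -0.70 (standard error 0.42), in the authors' deposited table. Mir132 and Mir212, which neuronal activity induces, both had a log2 fold change of -0.04 in the authors' deposited table, with standard errors of 0.25 and 0.24. The other 17 lists tested in brain had adjusted p from 0.175 to 0.959.

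In spleen, 0 of 1208 features passed with DESeq2 in the authors' deposited table, and the smallest adjusted p was 0.988. An unadjusted p under 0.05 was given for 42 features, 32 of them positive and 10 negative. The 42 are below a share of 0.05, the share to be had where no feature differs. Mir7j (log2 1.07, standard error 0.35), Gm55532 (log2 0.93, standard error 0.31) and Mir19b-1 (log2 0.77, standard error 0.27), the last from the miR-17/92 cluster, had positive values in the authors' deposited table. Mir7015 had a log2 fold change of -1.18 (standard error 0.41) in the authors' deposited table, and Mir466c-2 had 46 recovered reads on the negative and 2 on the positive side. The leukocyte list had an adjusted p of 0.814, and its members ran from log2 -0.12 (standard error 0.22) for Mir150 to 0.32 in the authors' deposited table. The abundant Mir143, Mir21a and Mirlet7g had log2 fold changes of -0.47 (standard error 0.30), 0.10 (standard error 0.23) and 0.00 (standard error 0.21) in the authors' deposited table. None of the 17 lists tested passed, and their adjusted p ran from 0.411 to 0.956. The let-7 list in spleen had a negative sign in 7 of 10 members, with a median of -0.04 and an adjusted p of 0.956.

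**Figure D2:**
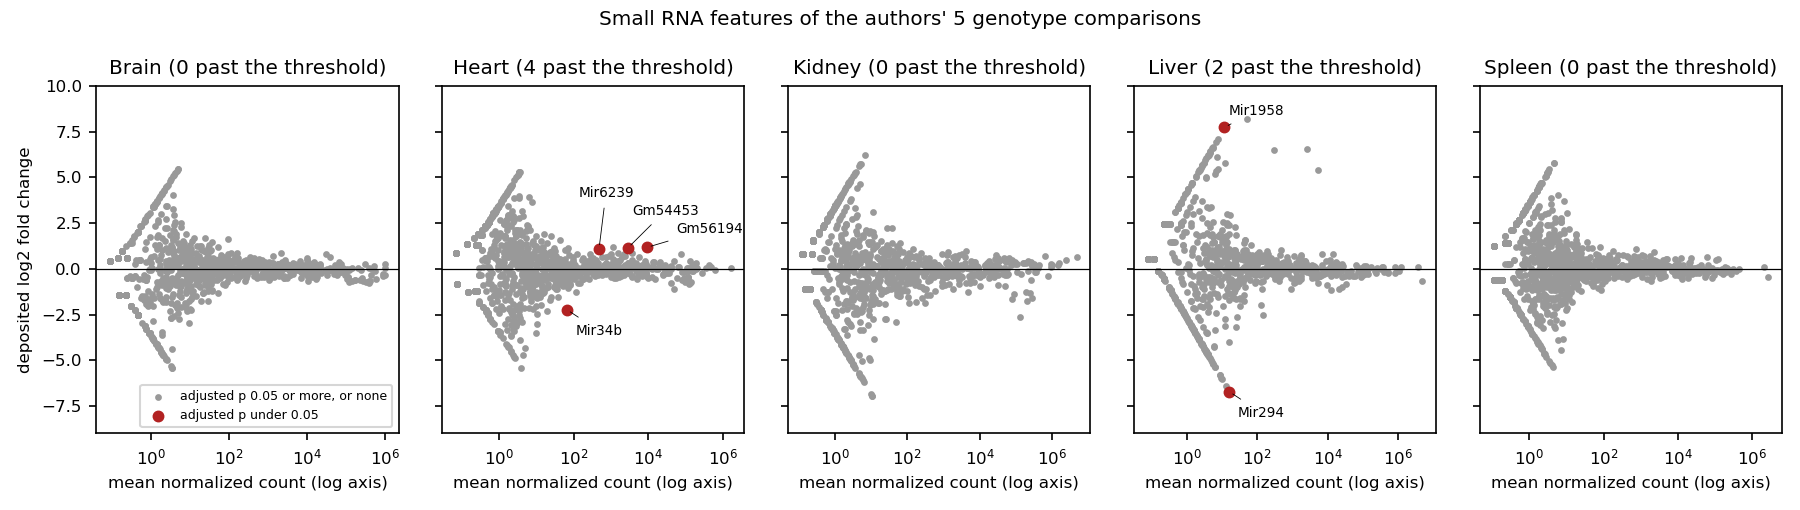
Log2 fold change between the genotypes (numerator not stated) against mean normalized count on a log axis, 1 panel per organ and 1 point per feature, from the authors' deposited tables. Features in red passed an adjusted p of 0.05, which 4 did in heart, 2 in liver and 0 in brain, kidney and spleen.

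**Figure D3:**
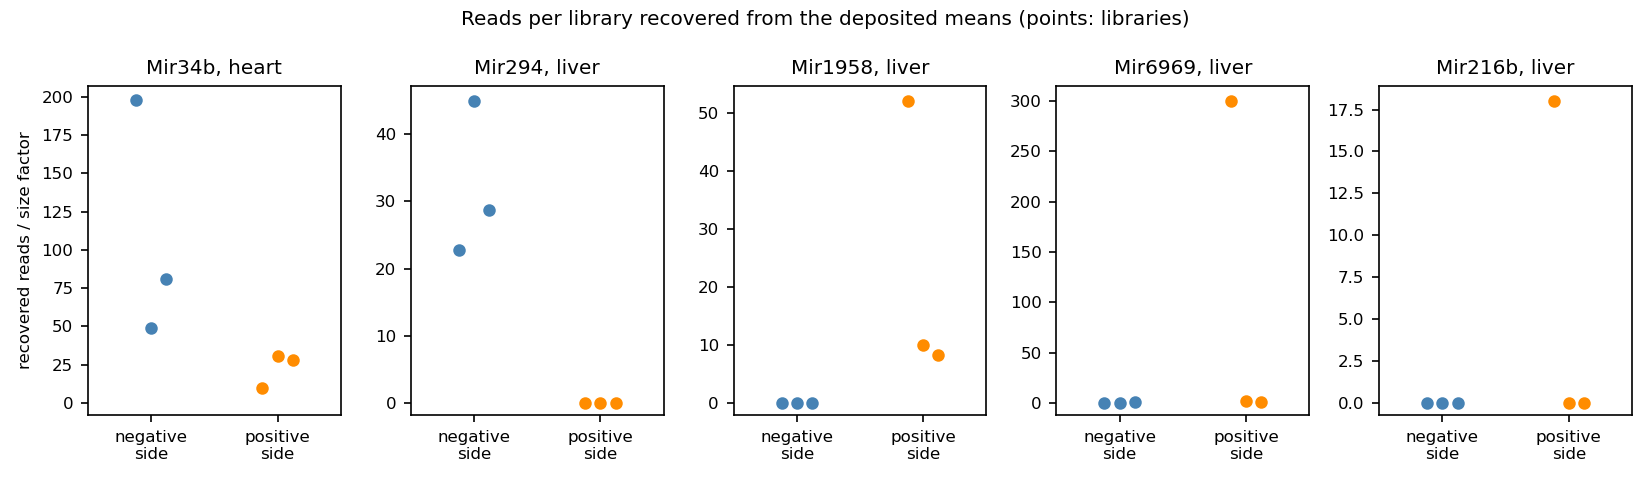
Recovered reads divided by the library's size factor for Mir34b in heart and Mir294, Mir1958, Mir6969 and Mir216b in liver, 1 point per library, grouped by the side of the fold change. Mir294 stands at 22.7, 44.9 and 28.8 on the negative side and 0 on the positive side, while 1 library of the positive side holds nearly all of Mir6969 and all of Mir216b.

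**Figure D4:**
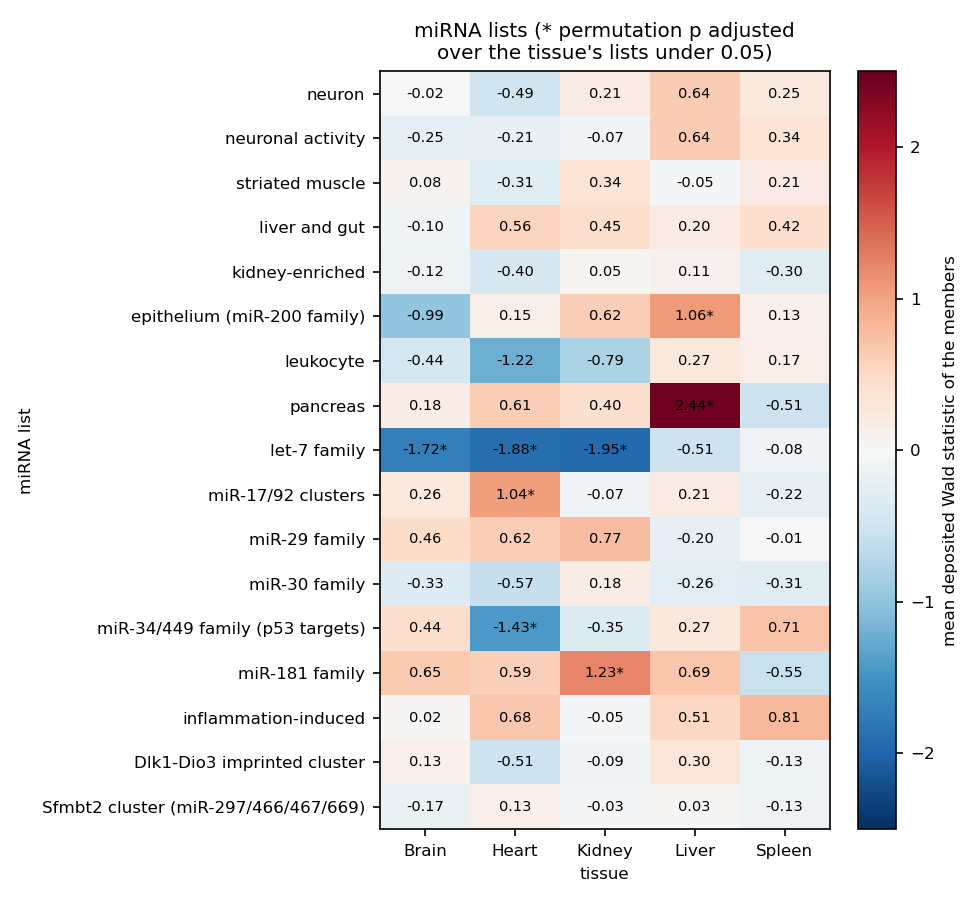
Mean deposited Wald statistic over the measured members of each microRNA list (vertical) in each organ (horizontal), with an asterisk where the permutation p adjusted over the organ's lists is under 0.05. The let-7 family carries it in brain, heart and kidney, at -1.72, -1.88 and -1.95, and the pancreas list in liver, at 2.44.

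Across organs, 0 features passed an adjusted p of 0.05 in 2 or more of them, by DESeq2 in the authors' deposited tables. At an unadjusted p under 0.05, 25 features did so, 21 of them with 1 sign throughout. Of these 21, 14 were positive and 7 negative. Heart and spleen shared 10 with the same sign, 9 of them Gm-named, against 1.33 expected from independent lists, and 2 with opposite signs. Heart and kidney shared 8 with the same sign against 1.22, and 5 of them were let-7 members, copies of let-7a and let-7c included. Heart and liver shared 0 against 1.05, and kidney and spleen shared 0 with the same sign against 0.616 and 2 with opposite signs. Of the features tested with DESeq2 in both organs, 53 in heart and 32 in liver had an unadjusted p under 0.05, and 45 in kidney and 34 in spleen. Mir125a and Mir125b-1, named here after their values were seen, are transcribed in clusters with let-7 genes and were negative in 4 of 5 organs, the exception being spleen. In the authors' deposited tables Mir125a stood at log2 -1.77 (standard error 0.62) in kidney and 0.39 (standard error 0.25) in spleen. Spearman's rho of log2 fold changes, across features with a mean of at least 10, was 0.36 for heart and kidney, 0.33 for kidney and liver and 0.31 for heart and liver. At a mean of at least 100 these were 0.51, 0.46 and 0.36. For spleen with the other 4 organs rho lay between -0.02 and 0.07 at a mean of at least 10. It lay between -0.04 and 0.19 at a mean of at least 100. Heart, kidney and liver are also the organs with a library of the second batch, which was not separated from these values. Features are not independent replicates, and the same 6 mice gave every organ, so these values describe the tables and carry no p.

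By permutation of features, the let-7 fold change differed between organs. Let-7 was the only list compared in this way, and it was chosen after its values were seen. Kidney lay below spleen by a median log2 difference of -1.22 over the 10 members and below liver by -0.99 (permutation p = 1e-05 each, the smallest the draws can give). Brain and heart did not differ detectably from each other (permutation p = 0.927), nor did liver and spleen (permutation p = 0.124). Single features were also compared between organs by an approximate z-score, and 0 of 8380 differences passed, with a smallest adjusted p of 0.336 and 229 at an unadjusted p under 0.05, from DESeq2 values in the authors' deposited tables. The 229 are below a share of 0.05, the share to be had where no feature differs. The largest of these z-scores was that of Mir3474, at log2 -5.90 in kidney and 5.79 in liver in the authors' deposited table. The standard error of that difference was 2.85. The lower of the feature's means in the 2 organs was 5.19 normalized counts, under the minimum of 10 used for other values. Permuting features ignores shared reads and variation between mice, and no test over mice was run for the lists. The z-scores treat the organs as independent, though the same mice gave all of them. Heart, kidney and liver hold a library of the second batch and brain and spleen do not, so batch was not separated from these differences.

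**Figure D5:**
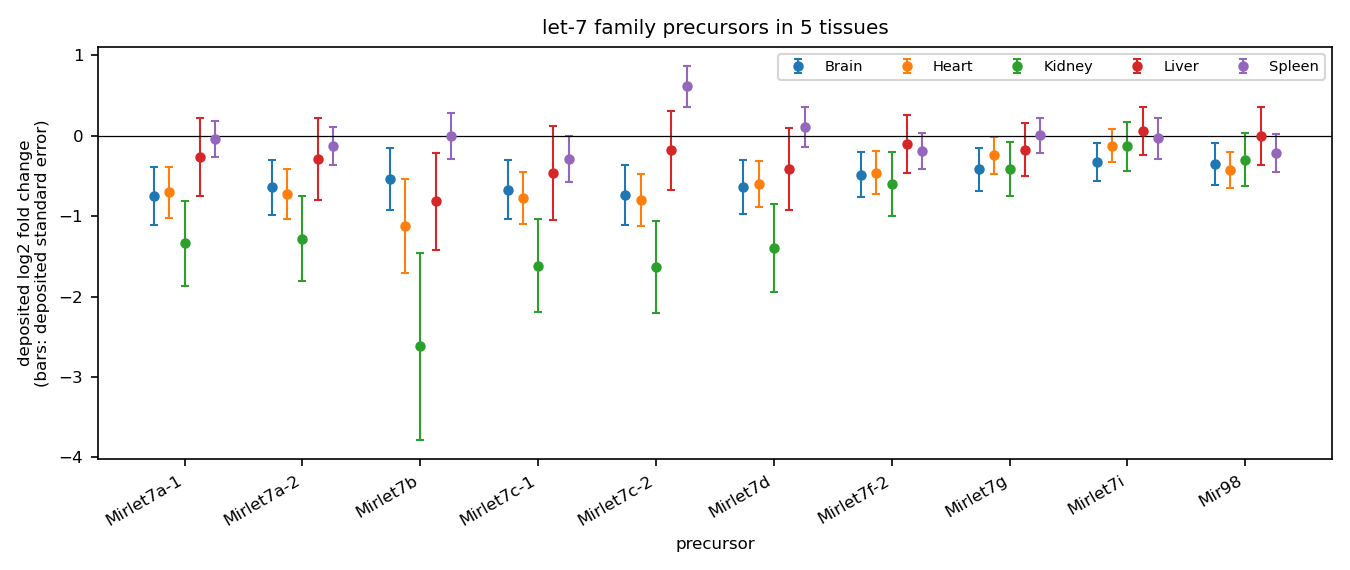
Log2 fold change of each of the 10 measured let-7 family members in each organ, with the standard errors of the authors' deposited tables. All 10 are negative in brain, heart and kidney, 9 in liver and 7 in spleen.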

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

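The tests of let-7 between organs, of spleen RNA in liver, of shared let-7 reads and of the let-7 batch were chosen after the results were seen.

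By permutation of features, which ignores variation between mice, the let-7 family had a fold change that differed between organs. No other list was compared between organs. The median log2 difference over 10 members was 0.61 for brain minus kidney, -0.35 for brain minus liver, -0.47 for brain minus spleen, 0.59 for heart minus kidney, -0.33 for heart minus liver, -0.54 for heart minus spleen, -0.99 for kidney minus liver and -1.22 for kidney minus spleen. With 1 precursor per mature sequence the largest permutation p over brain, heart and kidney was 0.00066, which argues against repeated copies in the list as the whole cause. It leaves the counting unchanged, so reads shared between different let-7 members could not be tested. Brain holds no library of the second batch and its list had a permutation p of 1e-05, the smallest the draws can give. That batch therefore cannot account for the brain values, but by design this bears on brain alone, since the heart and kidney libraries are others. In heart and kidney the batch and the genotypes cannot be told apart, because 0 of their let-7 members were low enough to be split into libraries. A difference between genotypes may contribute, and so may variation between the mice or a single library, since neither could be tested without values per library.

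Pancreas microRNAs had large positive fold changes in liver, in features that carry a statistic and no p-value: log2 6.52 for Mir216a, 6.55 for Mir217 and 5.42 for Mir375 in the authors' deposited table. Mir6969, which lies in the colipase gene Clps and was chosen after its values were seen, had 8.20 there. Of its 154 recovered reads, 97.4% came from the library that also held all 9 Mir216b reads, and the other 2 libraries of that side held 2, which argues against a difference in all libraries of the side. Spleen RNA would raise leukocyte microRNAs, whose median log2 fold change in liver was 0.082. Pancreas RNA in 1 liver library is a candidate explanation, and the genotype of that library could not be identified from the values.

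The other features with a statistic and no p-value had smaller values. In the authors' deposited table for kidney, Mir7b had a log2 fold change of -1.12, Mir8120 of -1.85 and Mirlet7b of -2.62, the last too abundant to be split into libraries. Of the 98 recovered Mir8120 reads, 74 came from 1 library, and without it the positive side was the higher, at least 4.62-fold. Mir466n had -1.52 in the authors' deposited table for liver, with 73 of 79 reads in 1 library. Without that library the positive side was the higher for Mir466n too, 3.27-fold against the floor. This rests on 6 reads, all from 1 library, taken as counted, so it is no firm bound.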

How the results depend on the processing

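The sign test, 1 precursor per mature sequence, the mean of at least 10 for lists, the mean of at least 100 for correlations, the treatment of features without a p-value and the folds without the highest library were chosen after seeing the data. Of 56 counts under an alternative, 42 equalled the main count and 14 did not. Of 44 values of named features, 41 stayed on the same side of the threshold. Most of the 44 belong to features that did not pass in the main setting, so this count says little about the calls. Some of the equal counts were fixed in advance, since a stricter threshold or a minimum size cannot add to a count of 0. Brain, heart and spleen also have no feature with a statistic and no p-value to leave out. In heart, 1 feature passed when the adjustment ran over all p-values, where more features share the correction, 13 at an adjusted p under 0.1 and 1 at 0.01. Mir6239, Gm54453 and Mir34b, of the 4 features past the threshold in heart, were the 3 named features that no longer passed. In liver 0 passed at 0.01. With the features lacking a p-value taken in, 3 passed in liver in place of 2. The lists past the threshold in heart numbered 3. With unmatched draws they numbered 5 (Dlk1-Dio3 and leukocyte joined), with a mean of at least 10 they numbered 4 (Dlk1-Dio3 joined), and with 1 precursor per mature sequence 2 (miR-17/92 lost). The heart sign test also called 3, but only let-7 was shared with the permutation, since neuron and Dlk1-Dio3 passed and miR-17/92 did not, while the combined miR-34 and miR-449 list is too short for the sign test to pass after adjustment. The same holds for miR-181 in kidney and for the miR-200 and pancreas lists in liver, so the counts of 1 and 0 with the sign test there say nothing about these lists. In liver the lists numbered 1 with unmatched draws and 1 over features with a mean of at least 10 (miR-200 lost). Without features lacking a p-value 1 remained, because the pancreas list kept fewer than 3 members and was not tested. For the other changes the cause was not tested. At an unadjusted p under 0.05, 25 features were shared between organs. The median rho between organs was 0.12, and 0.22 at a mean of at least 100. No paired analysis was possible because the tables carry no values per library, and the recovered reads cover low features of libraries not assigned to mice. For the same reason other normalizations, count models and count filters, the litter block, leaving out each library over all features or the second batch, pseudocounts, set tests on counts and the model of 30 libraries were not run, and other splits of the samples could not be counted. Read counts limit the low features, whose calls in liver rest on 38 and 164 reads.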

Other observations

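Features with provisional Gm symbols, whose class was examined after seeing the data, had higher statistics than features of the same level in 4 of 5 organs. Of those with a mean of at least 10, 35 of 43 were positive in heart (median log2 fold change 0.50), 40 of 48 in spleen (0.50), 24 of 30 in liver (0.39), 20 of 36 in kidney (0.05) and 18 of 31 in brain (0.09). The class gave a permutation p of 5e-05 in heart and in spleen, the smallest the draws can give, of 0.0285 in liver, 0.009 in kidney and 0.517 in brain. Adjusted over the 5 organs these were 0.000125 in heart and spleen, 0.0356 in liver and 0.015 in kidney. Permuting features treats them as independent and ignores shared reads and variation between mice. For this class neither shared reads nor a difference over mice was tested. The draws were matched on mean level, which argues against level as the whole cause. The spleen value was set in advance as evidence against the second batch in heart, but by design it bears on spleen alone, since the heart libraries are others. In heart the batch and the genotypes cannot be told apart for this class. Of its features with a mean of at least 10, 17 were low enough to be split into libraries, and these did not show the lean clearly with all 6 libraries (11 of 17 positive, permutation p = 0.107), so leaving out single libraries decided nothing. The others were too abundant to be split. Gm54610 and Gm54588, chosen after their values were seen, had log2 fold changes of 0.42 (standard error 0.20) each in heart, and 0.56 and 0.64 in spleen, in the authors' deposited tables. They stood at 0.25 and 0.26 in brain, -0.35 and 0.00 in kidney and -0.40 and -0.29 in liver in the same tables. Mir6236, chosen likewise, had 0.82 (standard error 0.28) in heart.

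The spleen table also held pancreas microRNAs, at 0.185% of its total for Mir375 and 0.119% for Mir217 in the authors' deposited table, with log2 fold changes of -0.23 (standard error 0.90) and -0.54 (standard error 0.80). Mir802, of liver and gut and chosen after its values were seen, was positive in both organs where its unadjusted p was under 0.05, at log2 0.92 (standard error 0.36) in kidney and 0.80 (standard error 0.40) in liver in the authors' deposited tables. The inflammation-induced list and the Sfmbt2 cluster each had an adjusted p of 0.411 in spleen. The miR-29 and miR-30 lists did not pass in any organ. Lists with fewer than 3 measured members in an organ, among them smooth muscle (Mir143, Mir145a), red cell (Mir144), endothelium (Mir126a) and hypoxia (Mir210), gave 46 member values, of which 0 had an unadjusted p under 0.05 from DESeq2 in the authors' deposited tables. These lay between -0.65 and 0.76.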
